A study of Mus musculus with 18 samples.

How the data were processed

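Thymi of C57BL/6 mice were dissociated, passed through a nylon mesh strainer, washed to remove fat cells and treated with ammonium chloride to lyse red cells, per the labels. Thymocyte RNA was prepared with an RNeasy kit, amplified and labelled by linear amplification, and hybridized to 9 Agilent 2-colour mouse arrays. The 18 samples are the 2 channels of these arrays: Cy3 for 3 mice each of 6, 16 and 24 months, and Cy5 for the 1 month reference on every array. Both samples of an array carried an identical scanner file on all 9 arrays. The design calls the 1 month reference a pool, while the sample labels describe single numbered 1 month mice, and the files do not settle which holds. It was treated as 1 control sample.

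The scanner files hold intensity values per feature as deposited: raw mean signals with local background, and processed signals that the authors' software had background-subtracted and normalized between the dyes by LOWESS with a smooth factor of 0.25, per the file headers. The headers name Agilent Feature Extraction 7.5.1, the submitters' processing notes version 7.1. All 9 arrays had the same extraction settings and 1 extraction day. The deposited value table holds a score per channel, which was checked to be the z-score of the log10 processed signal within the channel, as made by the authors.

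Each array has 43790 features, of which 41534 are not controls, for 41174 distinct probes. Raw signals were background-corrected with normexp (offset 50) from the mean signal and the median local background, and log ratios of Cy3 to Cy5 were normalized within arrays by loess, in limma 3.58.1 under R 4.3.3. Positive values mean higher in the older mouse. Spots marked as outliers by the scanner software were left out, 34 to 52 per array but 159 and 179 on 24 month replicates 1 and 3, and replicate spots of a probe were averaged. A probe was tested when it was well above background in Cy3 on all 3 arrays of at least 1 age, or in Cy5 on all 9 arrays. This left 37449 probes, of which 14612 carried a usable gene symbol for 11930 genes. Saturation was reached by 133 tested probes on at least 1 array. Gene symbols were updated through 12204 RefSeq accessions of probes, of which 11450 matched a current gene, through synonyms, and for 785 probes through their description. Tables were prepared in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, figures were drawn with matplotlib 3.10.9, and exact permutation tests were run in R.

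One limma model with a mean per age was fitted to all 9 arrays with empirical Bayes moderation (prior degrees of freedom 2.80, residual 6). The 3 contrasts between ages compare 3 arrays with 3, and an F test covers any difference among the ages. An age against the pool tests the mean of 3 log ratios against 0, which leaves out the spread between 1 month mice if the reference is 1 pool, and cannot separate age from dye. A probe passed at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Gene lists, 38 in number, were fixed before the data were examined from knowledge of the thymus, T cells, ageing and other cell types of a thymus suspension. They were tested with camera of limma over 34575 distinct names, called genes in the list tests. Besides the 11930 usable symbols these names include accession and clone names of probes without one. Each name had 1 probe (the one with the highest mean intensity). The preset correlation between genes was 0.01, with Benjamini-Hochberg adjustment over the lists. A list was called at an adjusted p under 0.05. The adjusted p with a correlation estimated from the data, under which 0 lists were called, is given beside each call. After the data were seen, 2 lists matched on probe descriptions were added for immunoglobulin and T cell receptor segments.

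The genes named in the text were chosen by a rule fixed before the data were examined, as were the comparisons and the alternative settings not said below to have been added later. Among probes past the threshold with arrays of the ages not overlapping, or with 3 log ratios of one sign against the pool, and with a usable symbol, it takes 1 probe per gene. The 10 largest rises and falls were taken for 24 against 6 months, 16 against 6 months and 24 months against the pool, and 5 and 5 for the other comparisons. Where none passed, the 5 genes with the smallest p were taken. Up to 4 members of each list past the threshold with the largest change were added, or up to 2 with the smallest p, as values, where none passed. After the values were seen, the printed list members were narrowed to lists of interest in that comparison, mostly those called. Genes saturated in Cy5 are given no fold and no direction, and where the rule had picked such probes among the rises, the next unsaturated rises were taken in their place.

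The model was tested on simulated data with 200 changed probes added to noise that was independent between arrays and between probes. At 24 against 6 months it found 31.3% of 67 probes changed 1.5-fold, 62.7% of 67 changed 2-fold and 98.5% of 66 changed 4-fold, with 10 false of 142 calls. At 24 against 16 months the shares were 28.4%, 64.2% and 98.5%, with 7 false of 137. At 24 months against the pool they were 62.7%, 77.6% and 100%, with 10 false of 176. A simulated 1.5-fold shift of the DNA replication list was called at 24 against 6 months (adjusted p = 6.58e-20), with 0 of the 37 other lists. At 24 against 16 months and at 24 months against the pool it was called too (adjusted p = 2.79e-15 and 1.36e-30), with 1 of the 37 other lists each. As the simulated probes were not correlated with each other, these counts do not show how often lists are called falsely in the real data. The shares found hold for randomly drawn probes with noise not shared between arrays. They do not give the power for real genes, which may vary more between mice.

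Alternatives were Agilent's processed signals, median centring, scale normalization between arrays, no filter and a strict filter on dim probes (31689 probes), outlier spots kept, an intensity trend with robust moderation, a replicate block, the authors' scores, only the compared ages in the fit, the Cy3 channel alone, and a separate-channel fit of the 1 month channels (statmod 1.5.0, intraspot correlation 0.695). The separate-channel fit counted the 9 Cy5 channels as 9 samples. If the reference is 1 pool, these are repeats of 1 control sample and not replicates. Median centring shifts each array by 1 value and, unlike loess, does not correct a dye difference that changes with intensity. Each array was also left out in turn. For the lists, an estimated correlation and the mean over all probes of a gene were tried. Alternatives added after seeing the data left out saturated probes, the 2 arrays that stood apart (16 month replicate 1 and 24 month replicate 3) or the 3 arrays highest in haemoglobin (these and 16 month replicate 2), or took haemoglobin as a covariate. Replicate numbers do not pair the arrays: of 9 correlations between the deviations of arrays with the same number, 2 were over 0.1. The number of probes at background limits the genes covered. Control features were not used here.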

Results

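Gene expression was measured in isolated mouse thymocytes, the developing T cells of the thymus, on 9 Agilent 2-colour arrays. Each array carried a Cy3 sample from 1 C57BL/6 mouse aged 6, 16 or 24 months, with 3 mice per age, and a Cy5 sample of 1 month thymocytes. The design describes the 1 month material as a pool, whereas the sample labels number 9 1 month mice. The median probe varied across the 9 Cy5 channels with an SD of 0.11 on the log2 scale, against a median SD of 0.15 within an age for the Cy3 channels. Between 79.6% and 94.2% of the non-control features were well above background in Cy3, and between 90.5% and 95.4% in Cy5. The median Cy3 signal over background was lowest on 24 month replicate 2 (61.2) and highest on 6 month replicate 1 (175). After filtering, 37449 probes were tested. Values are log2 ratios with the SE from limma on 3 arrays per age. A gene named as higher or lower than the pool had all 3 log ratios of that age on the stated side of 0. No array had the dyes swapped, so an age compared with the pool is also Cy3 compared with Cy5. The number of arrays limits the precision.

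The comparison of 6 months with the 1 month pool covers the first interval of the series. Ccl25, a chemokine made by thymic epithelium that draws T cell precursors into the thymus, was 4.31-fold lower at 6 months (log2 ratio -2.11, SE 0.13, adjusted p = 0.000899). The epithelial keratin genes Krt18 (-1.17, SE 0.14) and Krt8 (-0.70, SE 0.16) also fell, with adjusted p of 0.0031 and 0.022. The cortical epithelial protease gene Prss16 fell by 1.02 (SE 0.10, adjusted p = 0.0019), while a further probe of it had the opposite sign. The transcription factor gene Nfkb1 fell by 0.83 (SE 0.12, adjusted p = 0.00629). The granulocyte gene S100a8 fell by 2.27 (SE 0.66, adjusted p = 0.0482). Of the 14 members of the thymic epithelium list, 7 fell and 0 rose, with the same counts adjusted over the list alone. The list was called lower (median -0.25, adjusted p = 0.00258, and adjusted p = 0.978 with an estimated correlation).

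In the list of T cell receptor complex and signalling genes, 10 of 23 members rose and 0 fell, or 11 and 1 adjusted over the list alone. They included Vav1 (0.70, SE 0.09), Lat (0.55, SE 0.08, and -0.14 with median centring), Zap70 (0.52, SE 0.10) and Nfatc1 (0.56, SE 0.14). The list was called higher (median 0.15, adjusted p = 0.002, and adjusted p = 0.978 with an estimated correlation), but its median was -0.28 with median centring of the arrays. Of 19 double-positive thymocyte genes 7 rose and 1 fell, or 9 and 3 adjusted over the list alone. This list was called higher (median 0.24, adjusted p = 0.0208, and adjusted p = 0.978 with an estimated correlation), with a median of -0.33 after median centring. Its members included Cd2 (0.56, SE 0.10), Ly6d (0.65, SE 0.10) and the chromatin organiser gene Satb1 (0.38, SE 0.07). Of these, Ly6d stood at -0.09 and Satb1 at -0.38 with median centring. Of 22 heat shock and unfolded protein genes 10 rose and 1 fell, or 12 and 1 adjusted over the list alone. Camera called the list higher (median 0.26, adjusted p = 0.00258, and adjusted p = 0.978 with an estimated correlation), with a median of -0.14 after median centring. Members that rose included the chaperone genes Stip1 (0.71, SE 0.18) and Hspa8 (0.70, SE 0.20, and -0.08 with median centring). The stress response regulators Atf4 (0.58, SE 0.10) and Hsf1 (0.53, SE 0.07) rose with them.

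Of 26 replication-dependent histone genes, which are transcribed in S phase, 6 rose and 1 fell, or 8 and 1 adjusted over the list alone. The list was called higher (median 0.32, adjusted p = 0.00131, and adjusted p = 0.978 with an estimated correlation), with a median of -0.06 after median centring. Of 68 ribosomal protein genes 24 rose and 5 fell, or 28 and 5 adjusted over the list alone. This list was called higher (median 0.19, adjusted p = 0.000909, and adjusted p = 0.978 with an estimated correlation), with a median of -0.49 after median centring. Without saturated probes its adjusted p was 0.805. A list of 32 T cell receptor segment probes was matched on their descriptions after the data were seen. Of these 10 rose and 0 fell, or 11 and 0 adjusted over the list alone. In the list test it was called higher (median 0.10, adjusted p = 0.00226, and adjusted p = 0.978 with an estimated correlation), with a median of -0.08 after median centring. The erythroid list, in contrast, had all 10 members below the pool and was not called (median -0.12, adjusted p = 0.0594). The largest rises left once saturated probes were passed over were those of the splicing gene Snrpd3 (1.18, SE 0.19) and Arhgap45 (1.12, SE 0.18). The chromatin genes Baz2a (1.10, SE 0.27) and Chd1 (1.05, SE 0.26) and the T lineage transcription factor gene Bcl11b (1.02, SE 0.23) followed. These 5 genes were chosen after their values were seen.

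At 6 months 6215 of the 37449 probes passed the threshold against the pool, 3345 higher and 2870 lower, of which 45 differed by more than 2-fold. With the authors' scores 2475 were higher and 2788 lower, and with median centring 9189 and 10435, so that the balance turned. The count was 844 with haemoglobin as a covariate, 3928 with a replicate block, 9358 in a separate-channel fit, 2070 without 6 month replicate 1 and 489 without 6 month replicate 2. With haemoglobin as a covariate 15 of the 22 genes named here no longer passed, and 1 of the 6 list calls ended, that of histones (adjusted p = 0.0683). Without replicates 1, 2 and 3 of 6 months in turn, 10, 18 and 5 of the 22 genes named here no longer passed.

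The comparison of 16 months with the pool reaches mid-life. Cxcr6, a chemokine receptor of NKT and effector T cells, was 5.82-fold higher (2.54, SE 0.27, adjusted p = 0.00112). Jchain, which joins secreted immunoglobulin units, was 4.88-fold higher (2.29, SE 0.26, adjusted p = 0.00135). Ccl25 fell by 1.94 (SE 0.13, adjusted p = 0.000409) and Prss16 by 0.98 (SE 0.10, adjusted p = 0.000862). The cold-inducible RNA-binding protein gene Rbm3 (-1.43, SE 0.12), the respiratory chain gene Cox7b (-1.19, SE 0.14) and the Wnt receptor gene Fzd10 (-0.92, SE 0.09) fell as well. The largest rises left once saturated probes were passed over were those of the protease inhibitor gene Slpi (1.58, SE 0.29), the lysosomal gene Psap (1.40, SE 0.11) and the matrix proteoglycan gene Dcn (1.40, SE 0.33). These 3 genes were chosen after their values were seen.

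All 5 measured members of the immunoglobulin list rose at 16 months, and all 5 passed adjusted over the list alone, with Igkv19-93 at 0.86 (SE 0.20). The list was called higher (median 0.86, adjusted p = 0.00155, and adjusted p = 0.741 with an estimated correlation). Of 95 immunoglobulin probes matched on their descriptions after the data were seen, 65 rose and 2 fell, or 72 and 5 adjusted over the list alone. They were called higher (median 0.68, adjusted p = 3.5e-17, and adjusted p = 0.683 with an estimated correlation). Of 15 B cell genes 4 rose and 0 fell, with the same counts adjusted over the list alone, and the list was called higher (median 0.12, adjusted p = 0.045, and adjusted p = 0.741 with an estimated correlation). Of 9 plasma cell genes 3 rose and 0 fell, with the same counts adjusted over the list alone, and the list was called higher (median 0.20, adjusted p = 0.0152, and adjusted p = 0.741 with an estimated correlation). Members that rose included the receptor gene Cd79b (0.60, SE 0.14), the coactivator gene Pou2af1 (0.63, SE 0.17) and the secretory regulator Xbp1 (0.47, SE 0.10). Of 21 NK and cytotoxic genes 10 rose and 0 fell, or 12 and 0 adjusted over the list alone, and the list was called higher (median 0.30, adjusted p = 6.08e-05, and adjusted p = 0.741 with an estimated correlation). They included the granule gene Nkg7 (1.26, SE 0.17), the chemokine gene Ccl5 (1.11, SE 0.25), Klra7 (1.02, SE 0.17) and Il2rb (1.00, SE 0.16). The antigen presentation genes of MHC class II were above the pool for all 8 members, of which 3 rose, or 7 adjusted over the list alone. As a list they were called higher (median 0.46, adjusted p = 0.0056, and adjusted p = 0.741 with an estimated correlation), with H2-Ab1 at 1.36 (SE 0.20) and H2-Eb1 at 1.02 (SE 0.24). Of 19 macrophage genes 4 rose and 0 fell, among them the lysozyme gene Lyz1 (1.20, SE 0.23), and the list was not called (median 0.05, adjusted p = 0.178). Of 16 mature T cell genes 7 rose and 0 fell, or 7 and 2 adjusted over the list alone, with S100a6 at 1.33 (SE 0.21) and Ly6c1 at 1.12 (SE 0.24). This list was called higher (median 0.39, mean 0.44, adjusted p = 0.0197, and adjusted p = 0.741 with an estimated correlation), with a median of 0.08 and a mean of -0.04 after median centring. Haemoglobin moved with these groups, with a mean log ratio of 1.78, 1.19 and -0.67 on 16 month replicates 1, 2 and 3, against -1.75, -1.73 and -1.09 on the 6 month arrays. With it as a covariate 3 of the 11 list calls ended, those of B cells (adjusted p = 0.115), plasma cells (adjusted p = 0.0568) and DNA repair (adjusted p = 0.271). Without 16 month replicate 1 the calls of B cells (adjusted p = 0.179), plasma cells (0.12) and mature T cells (0.1) ended, and Pou2af1 stood at 0.38.

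Of 22 heat shock and unfolded protein genes 15 rose and 2 fell at 16 months, or 16 and 2 adjusted over the list alone. Camera called the list higher (median 0.46, mean 0.41, adjusted p = 4.94e-05, and adjusted p = 0.741 with an estimated correlation), with a median of 0.04 and a mean of -0.0084 after median centring. The endoplasmic reticulum genes Pdia4 (1.07, SE 0.19) and Calr (0.80, SE 0.09) were among those that rose. Of 72 oxidative phosphorylation genes 29 fell and 4 rose, or 33 and 9 adjusted over the list alone. They were called lower (median -0.17, adjusted p = 0.00155, and adjusted p = 0.741 with an estimated correlation), with Cox7c at -0.83 (SE 0.10) and the complex I gene Ndufs4 at -0.73 (SE 0.09). Of the 23 genes of the T cell receptor complex and signalling 9 rose and 0 fell, with the same counts adjusted over the list alone. They were called higher (median 0.12, adjusted p = 0.0152, and adjusted p = 0.741 with an estimated correlation), with a median of -0.17 after median centring, and included Zap70 (0.68, SE 0.10) and Vav1 (0.77, SE 0.09). Of 19 double-positive thymocyte genes 9 rose and 2 fell, with the same counts adjusted over the list alone, and Cd2 stood at 0.70 (SE 0.10). This list was called higher (median 0.21, adjusted p = 0.0279, and adjusted p = 0.741 with an estimated correlation), with a median of -0.27 after median centring. Of 29 DNA repair genes 7 rose and 0 fell, or 7 and 1 adjusted over the list alone, with Parp1 at 0.43 (SE 0.09) and Chek2 at 0.43 (SE 0.06). Together they were called higher (median 0.09, adjusted p = 0.0465, and adjusted p = 0.741 with an estimated correlation), with a median of -0.19 after median centring. The thymic epithelium list was not called (median -0.11, adjusted p = 0.0716). Of its 14 members 4 fell and 0 rose, or 6 and 1 adjusted over the list alone. The replication-dependent histone list had a median of -0.10, a mean of 0.04 and a test in the higher direction (adjusted p = 0.945). The double-positive call ended without 16 month replicate 1 (adjusted p = 0.235) and the T cell receptor complex call without 16 month replicate 3 (0.069). The DNA repair call ended without 16 month replicate 1 (0.051) or 2 (0.298), 24 month replicate 2 (0.0559) or 6 month replicate 2 (0.0516).

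At 16 months 9131 probes passed against the pool, 4851 higher and 4280 lower, and 158 by more than 2-fold. The balance was 4276 higher and 2469 lower with Agilent's processed signals, 3476 and 4132 with the authors' scores, and 6877 and 9775 with median centring. The count was 4320 with only the 16 month arrays in the fit, 2561 without 16 month replicate 2, 5055 without replicate 3, and 13 without the 3 arrays highest in haemoglobin, which leaves 1 array of 16 months. Without 16 month replicates 1, 2 and 3 in turn, 7, 11 and 1 of the 32 genes named here and 5, 1 and 1 of the 11 lists were no longer called.

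The comparison of 24 months with the pool covers the whole age range. Jchain was 4.59-fold higher (2.20, SE 0.26, adjusted p = 0.00179) and Dcn rose by 1.38 (SE 0.33, adjusted p = 0.0203), but stood at 0.79 without 24 month replicate 1, no longer past the threshold. The granulocyte genes S100a9 (-3.35, SE 0.85, adjusted p = 0.0257) and S100a8 (-2.47, SE 0.66, adjusted p = 0.0311) fell. The granulocyte list was not called (median -0.14, adjusted p = 0.111), with 4 members that fell and 1 that rose, or 7 and 1 adjusted over the list alone. Ccl25 fell by 1.49 (SE 0.13, adjusted p = 0.000888). The respiratory chain genes Cox7b (-1.06, SE 0.14) and Cox7c (-0.85, SE 0.10), the calcium channel gene Itpr1 (-0.84, SE 0.18) and Fzd10 (-0.87, SE 0.09) fell. Iftap (-1.01, SE 0.14), Pigp (-0.89, SE 0.13) and Mplkip (-0.87, SE 0.08) were lower as well.

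All 5 members of the immunoglobulin list were above the pool at 24 months, and 3 rose, or 3 adjusted over the list alone, with Igkv19-93 at 0.92 (SE 0.20). The list was called higher (median 0.57, adjusted p = 0.00726, and adjusted p = 0.686 with an estimated correlation). Of the 95 immunoglobulin probes matched on their descriptions, 38 rose and 0 fell, or 48 and 3 adjusted over the list alone. They were called higher (median 0.43, adjusted p = 2.68e-12, and adjusted p = 0.664 with an estimated correlation). All 8 MHC class II genes were above the pool, of which 3 rose, or 5 adjusted over the list alone, with H2-Eb1 at 1.05 (SE 0.24). As a group they were called higher (median 0.44, adjusted p = 0.00726, and adjusted p = 0.686 with an estimated correlation). Of 21 NK and cytotoxic genes 9 rose and 2 fell, or 10 and 2 adjusted over the list alone, with Ccl5 at 1.03 (SE 0.25) and Nkg7 at 0.68 (SE 0.17). This list was called higher (median 0.16, adjusted p = 0.0357, and adjusted p = 0.686 with an estimated correlation). Of 72 oxidative phosphorylation genes 28 fell and 5 rose, or 32 and 6 adjusted over the list alone. They were called lower (median -0.16, adjusted p = 0.00388, and adjusted p = 0.686 with an estimated correlation), with the complex III gene Uqcrfs1 at -0.64 (SE 0.05) and Ndufs4 at -0.69 (SE 0.09). Of 22 heat shock and unfolded protein genes 12 rose and 2 fell, or 13 and 3 adjusted over the list alone. The list was called higher (median 0.35, adjusted p = 0.00441, and adjusted p = 0.686 with an estimated correlation), with a median of -0.38 after median centring. Its members Pdia4 (0.81, SE 0.19) and Hspa8 (0.77, SE 0.20) rose, the latter standing at -0.57 with median centring. Of 68 ribosomal protein genes 26 rose and 14 fell, or 28 and 17 adjusted over the list alone. They were called higher (median 0.16, adjusted p = 0.0229, and adjusted p = 0.686 with an estimated correlation), with a median of -1.07 after median centring and of -0.0013 with the authors' scores. Without saturated probes the ribosomal list turned to the lower direction (adjusted p = 0.844). Of the 32 T cell receptor segment probes matched on their descriptions 6 rose and 2 fell, or 7 and 2 adjusted over the list alone. The test called them higher (median 0.09, adjusted p = 0.0449, and adjusted p = 0.664 with an estimated correlation), with a median of -0.23 after median centring. Haemoglobin had a mean log ratio of -1.71, 0.37 and 1.21 on 24 month replicates 1, 2 and 3, so that it differed widely within this age. The thymic epithelium list was not called (median -0.02, adjusted p = 0.367), with 3 members that fell and 0 that rose. Without 24 month replicate 1 the calls of MHC class II (adjusted p = 0.0685), NK and cytotoxic genes (0.0624) and receptor segments by description (0.0538) ended, and H2-Eb1 stood at 0.69, no longer past the threshold. The ribosomal call ended without 24 month replicate 2 (0.0632), the receptor segment call without 24 month replicate 3 (0.0887), and the NK and cytotoxic call without 24 month replicate 3 (0.108) or 6 month replicate 1 (0.0525).

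The largest rises at 24 months left once saturated probes were passed over were H2-Ab1 (1.30, SE 0.20), Cxcr6 (1.30, SE 0.27), Psap (1.27, SE 0.11) and S100a6 (1.25, SE 0.21). Arhgef1 (1.22, SE 0.21), Arhgap45 (1.22, SE 0.18), Ppp1r14c (1.17, SE 0.33, with a further probe of opposite sign) and Slpi (1.14, SE 0.29) followed. These 8 genes were chosen after their values were seen. At 24 months 8046 probes passed against the pool, 3711 higher and 4335 lower, and 116 by more than 2-fold. The balance turned to 5860 higher and 5234 lower in a separate-channel fit and to 2354 and 1798 with only the 24 month arrays in the fit. The count was 26554 with median centring, 4615 without the 3 arrays highest in haemoglobin, and 2352, 4323 and 5059 without 24 month replicates 1, 2 and 3 in turn. Without these replicates 14, 4 and 10 of the 28 genes named here and 2, 1 and 1 of the 6 lists were no longer called.

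**Figure D1:**
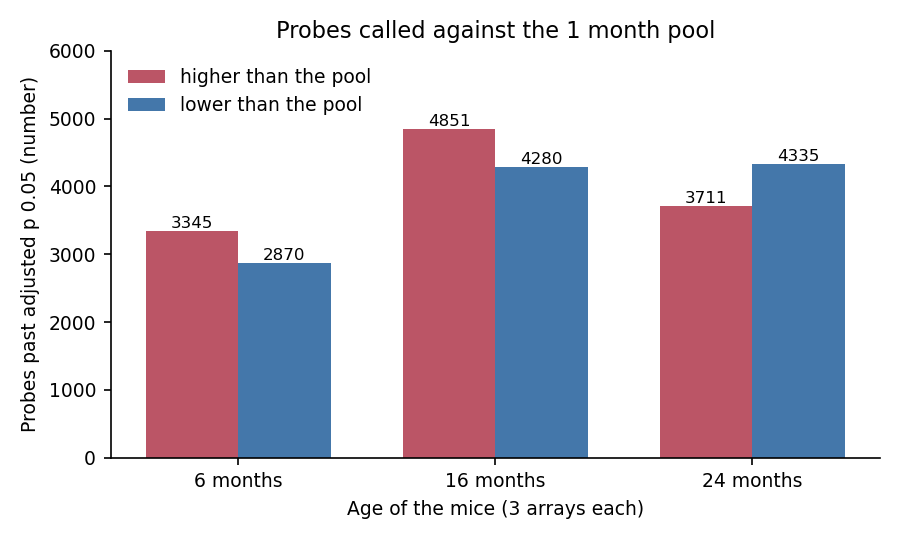
The bars count the probes past an adjusted p of 0.05 that were higher or lower at each age than in the 1 month pool: 3345 and 2870 at 6 months, 4851 and 4280 at 16 months, and 3711 and 4335 at 24 months. These balances turn with the authors' scores and with median centring at 6 and 16 months and in a separate-channel fit at 24 months.

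Setting the older ages against each other cancels the dye, and the 1 month reference too if it is 1 pool. The comparison of 24 with 6 months spans adult life. No single gene passed the threshold. Immunoglobulin genes were called higher at 24 months for all 5 members (median 0.57, adjusted p = 0.000867, and adjusted p = 0.339 with an estimated correlation). So were 90 of the 95 probes matched on their descriptions (median 0.41, adjusted p = 1.4e-21, and adjusted p = 0.327 with an estimated correlation). The array means of both lists did not overlap between the ages. Jchain was 3.42-fold higher at 24 months (1.77, SE 0.37, adjusted p = 0.437) and Igkv19-93 stood at 1.01 (SE 0.28, adjusted p = 0.495). Adjusted over the list alone, 2 of the 5 genes and 13 of the 95 probes passed. Thymic epithelium genes were called higher for 12 of 14 members (median 0.07, mean 0.27, adjusted p = 0.000893, and adjusted p = 0.339 with an estimated correlation). Adjusted over the list alone 5 were higher and 1 lower. Krt18 stood at 1.08 (SE 0.20, adjusted p = 0.437) and the epithelial transcription factor gene Trp63 at 0.46 (SE 0.10), with a further probe of opposite sign. Oxidative phosphorylation genes were called lower for 58 of 72 members (median -0.13, adjusted p = 1.75e-07, and adjusted p = 0.339 with an estimated correlation), with the complex I genes Ndufb3 at -0.45 (SE 0.10, on 2 of the 3 arrays of 6 months) and Ndufa6 at -0.36 (SE 0.08).

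Markers of several other cell types were called higher as well at 24 against 6 months. MHC class II was higher for all 8 members (median 0.37, adjusted p = 0.00256, and adjusted p = 0.423 with an estimated correlation), with H2-Ab1 at 0.68 (SE 0.29). Macrophage genes were higher for 16 of 19 (median 0.14, adjusted p = 0.000867, and adjusted p = 0.371 with an estimated correlation), with Lyz1 at 0.96 (SE 0.33) and the oxidase gene Cybb at 0.57 (SE 0.20). The macrophage list averaged 0.47, -0.09 and 0.18 on the 24 month arrays and -0.12, -0.18 and -0.07 on the 6 month arrays. Plasma cell genes were higher for 9 of 9 (median 0.14, adjusted p = 0.00634, adjusted p = 0.444 with an estimated correlation, 1 adjusted over the list alone), with Derl3 at 0.24 (SE 0.12). Dendritic cell genes were higher for 9 of 10 (median 0.08, adjusted p = 0.00919, adjusted p = 0.339 with an estimated correlation, 1 adjusted over the list alone), with Xcr1 at 0.29 (SE 0.07) and a further probe of it of opposite sign. B cell genes were higher for 12 of 15 (median 0.12, adjusted p = 0.016, and adjusted p = 0.371 with an estimated correlation). NK and cytotoxic genes were higher for 17 of 21 (median 0.07, adjusted p = 0.0394, adjusted p = 0.675 with an estimated correlation, 2 higher and 1 lower adjusted over the list alone), with Klrk1 at 0.37 (SE 0.07). Erythroid genes were higher for 9 of 10 (median 0.08, adjusted p = 0.00824, and adjusted p = 0.339 with an estimated correlation), with Eraf at 0.18 (SE 0.05). Replication-dependent histone genes were called lower for 21 of 26 (median -0.19, adjusted p = 0.00204, and adjusted p = 0.439 with an estimated correlation), with H1f1 at -0.22 (SE 0.07). Haemoglobin had a mean log ratio of -1.71, 0.37 and 1.21 on the 24 month arrays and of -1.75, -1.73 and -1.09 on the 6 month arrays. With it as a covariate 7 of the 17 calls on fixed lists ended, those of B cells (adjusted p = 0.0749), plasma cells (0.0813), erythroid (0.235), NK and cytotoxic (0.702), early thymocyte (0.0749), histone (0.359) and Notch pathway genes (0.121). The erythroid list itself holds haemoglobin genes, so the end of its call under this covariate says nothing further. In the Cy3 channel alone the calls of B cell (adjusted p = 0.128), erythroid (0.0565), Wnt (0.128) and interferon genes (0.142) ended. Without 24 month replicate 1 the calls of MHC class II (adjusted p = 0.233), B cells (0.126), plasma cells (0.0569), dendritic cells (0.0745) and NK and cytotoxic genes (0.137) ended, and H2-Ab1 stood at 0.40, Lyz1 at 0.64 and Cybb at 0.35. MHC class II averaged 0.94, 0.03 and 0.61 on the 24 month arrays and 0.28, 0.14 and 0.08 on the 6 month arrays, and without 24 month replicate 2 H2-Ab1 stood at 1.07. Without 24 month replicate 3 the calls of B cells (0.0623), plasma cells (0.062), erythroid (0.062), NK and cytotoxic (0.268) and histone genes (0.134) ended. The NK and cytotoxic call also ended without 6 month replicate 2 (0.129).

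Mature T cell genes were called higher for 11 of 16 members (median 0.31, adjusted p = 0.0457, and adjusted p = 0.675 with an estimated correlation), with a median of -0.02 after median centring. Early thymocyte genes were called higher for 13 of 21 (median 0.04, mean 0.07, adjusted p = 0.0458, and adjusted p = 0.339 with an estimated correlation), with a median of 0.03 and a mean of -0.02 after median centring and Erg at 0.16 (SE 0.05). Wnt pathway genes were called higher for 30 of 45 (median 0.04, mean 0.03, adjusted p = 0.0363, and adjusted p = 0.339 with an estimated correlation), with a median of 0.04 and a mean of -0.0038 after median centring and Wnt3 at 0.40 (SE 0.12). Notch pathway genes were called higher for 15 of 24 (median 0.06, adjusted p = 0.016, and adjusted p = 0.339 with an estimated correlation), with Hey1 at 0.22 (SE 0.08). Interferon response genes were called higher for 19 of 29 (median 0.09, adjusted p = 0.0458, and adjusted p = 0.714 with an estimated correlation). Inflammatory cytokine and chemokine genes were called higher for 23 of 30 (median 0.07, adjusted p = 0.00114, and adjusted p = 0.339 with an estimated correlation), with Ccl6 at 0.47 (SE 0.14). Without 24 month replicate 1 the calls of mature T cell (adjusted p = 0.602), early thymocyte (0.0569) and inflammatory genes (0.0809) ended, and Hey1 stood at 0.13. Those of early thymocyte (0.172) and Wnt genes (0.249) ended without 24 month replicate 2. Without 24 month replicate 3 those of mature T cell (0.133), early thymocyte (0.0612), Notch (0.0556) and interferon genes (0.0623) ended. Mature T cell calls also ended without 6 month replicate 1 (0.117) or 2 (0.0875) or 16 month replicate 1 (0.0528), and early thymocyte calls without 6 month replicate 2 (0.101) or 3 (0.168) or 16 month replicate 1 (0.066). Wnt calls ended without 6 month replicate 1 (0.117) or 3 (0.073), and interferon calls without 6 month replicate 1 (0.0898) or 3 (0.12) or 16 month replicate 3 (0.05).

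**Figure D2:**
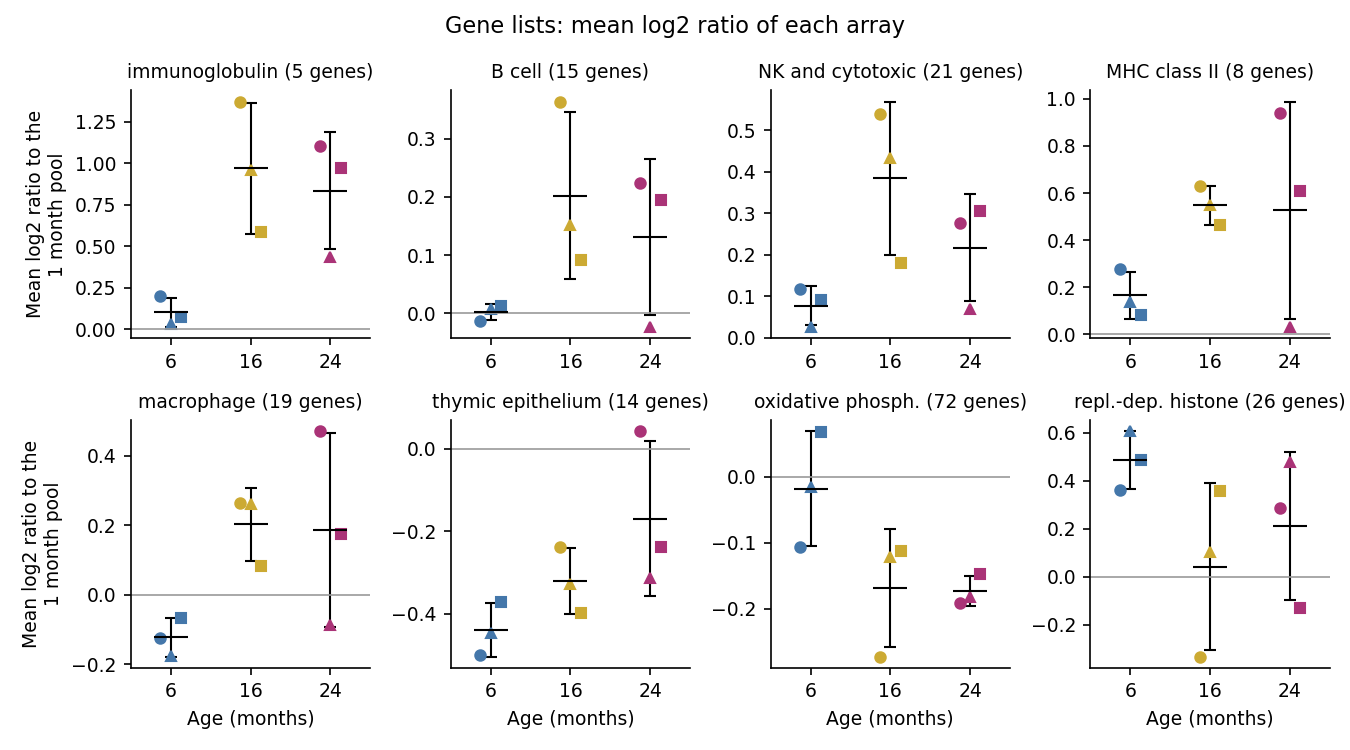
Each panel gives 1 gene list, with age in months on the x axis and the mean log2 ratio of the list to the 1 month pool on the y axis; circles, triangles and squares are replicates 1, 2 and 3, and the bar is the mean with its SD. The immunoglobulin list averaged 0.10 (SD 0.09, n = 3) at 6 months, 0.97 (SD 0.39) at 16 months and 0.84 (SD 0.35) at 24 months, while the histone list at 6 months has a median of -0.06 with median centring.

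Of the fixed lists not called at 24 against 6 months, DNA replication had a median of 0.00 (mean -0.02, adjusted p = 0.847). Mitosis also had 0.00 (mean -0.00 with a test in the higher direction, adjusted p = 0.902), and the CDK inhibitor and p53 target list -0.02 (adjusted p = 0.847). Medians were -0.05 for double-positive thymocytes (adjusted p = 0.409), -0.07 for the T cell receptor complex and signalling (adjusted p = 0.136) and 0.00 for regulatory T cells (adjusted p = 0.647). T cell receptor segments had 0.04 by symbol (adjusted p = 0.47) and -0.02 by description (adjusted p = 0.415). Among other cell types, adipocytes had 0.04 (adjusted p = 0.0832), stroma and vessels 0.05 (adjusted p = 0.13), and collagenase and matrix remodelling 0.04 (adjusted p = 0.0831). Granulocytes had -0.01 (mean -0.07, test in the higher direction, adjusted p = 0.647). Stress lists had -0.05 for apoptosis (adjusted p = 0.296), -0.04 for DNA repair (adjusted p = 0.337) and 0.03 for heat shock and unfolded protein (adjusted p = 0.808). Oxidative stress defence had -0.05 (adjusted p = 0.647), the glucocorticoid response 0.03 (adjusted p = 0.416) and immediate early genes 0.04 (adjusted p = 0.115). Ribosomal proteins had -0.02 (adjusted p = 0.617) and the proteasome -0.04 (adjusted p = 0.168, 2 lower adjusted over the list alone). Splicing (-0.01, adjusted p = 0.996) and sex-linked genes (-0.03, adjusted p = 0.996) had a test in the higher direction.

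In limma 0 of 37449 probes passed at 24 against 6 months (smallest adjusted p = 0.384). At an unadjusted p under 0.05 there were 3192, of which 1322 were higher and 1870 lower, against 1872 for chance. The 3 arrays of each age did not overlap for 14.8% of the probes, where chance gives 10%. The 5 genes with the smallest p, which did not pass (adjusted p = 0.437), were Tmem107 (0.87, SE 0.14), the proteasome gene Psma4 (-0.37, SE 0.06), the potassium channel gene Kcnj12 (0.32, SE 0.05), Zfp574 (0.39, SE 0.07) and Cypt4 (0.30, SE 0.05). The count was 0 in the other normalizations and filters, 1 with only the compared ages in the fit and 2 without 16 month replicate 3. Without replicates 1, 2 and 3 of 24 months in turn 8, 2 and 9 of the 17 list calls ended, 3 did without each 6 month array, and the interferon list turned to the lower direction without 24 month replicate 1 (adjusted p = 0.795).

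The comparison of 16 with 6 months covers the first part of that span. Cxcr6 was 3.84-fold higher at 16 months (1.94, SE 0.38) and Jchain 3.63-fold (1.86, SE 0.37), on arrays that did not overlap between the ages, at an adjusted p of 0.60 for both. Immunoglobulin genes were called higher for 5 of 5 members (median 0.92, adjusted p = 9.45e-06, adjusted p = 0.508 with an estimated correlation, 4 adjusted over the list alone), with Igkv19-93 at 0.95 (SE 0.28). So were 87 of 95 probes matched on their descriptions (median 0.64, adjusted p = 7.96e-35, adjusted p = 0.468 with an estimated correlation, 41 adjusted over the list alone). NK and cytotoxic genes were called higher for 17 of 21 members (median 0.27, adjusted p = 2.06e-07, adjusted p = 0.508 with an estimated correlation, 4 adjusted over the list alone), with Ccl5 at 1.45 (SE 0.36) and Klrk1 at 0.30 (SE 0.07). Replication-dependent histone genes were called lower for 23 of 26 (median -0.27, adjusted p = 7.46e-07, adjusted p = 0.508 with an estimated correlation, 1 adjusted over the list alone), with H2bc1 at -0.37 (SE 0.08). Oxidative phosphorylation genes were called lower for 58 of 72 (median -0.10, adjusted p = 1.09e-07, and adjusted p = 0.508 with an estimated correlation), with Ndufb3 at -0.44 (SE 0.10, on 2 of the 3 arrays of 6 months) and Atp5j2 at -0.54 (SE 0.14).

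B cell genes were called higher at 16 against 6 months for 13 of 15 members (median 0.12, adjusted p = 0.00206, and adjusted p = 0.508 with an estimated correlation), with Cd79b at 0.53 (SE 0.19). Plasma cell genes were called higher for 9 of 9 (median 0.19, adjusted p = 0.000103, adjusted p = 0.508 with an estimated correlation, 4 adjusted over the list alone). Macrophage genes were called higher for 15 of 19 (median 0.13, adjusted p = 0.000376, adjusted p = 0.512 with an estimated correlation, 4 higher and 1 lower adjusted over the list alone), with Lyz1 at 1.28 (SE 0.33) and Lyz2 at 1.36 (SE 0.37). Granulocyte genes were called higher for 14 of 16 (median 0.36, adjusted p = 0.00068, and adjusted p = 0.549 with an estimated correlation), with Chil3 at 0.44 (SE 0.21). The granulocyte list averaged -0.27, 0.81 and -0.63 on the 16 month arrays and -0.58, -0.51 and -0.36 on the 6 month arrays. Its direction turned without the 3 arrays highest in haemoglobin, which leaves 1 array of 16 months. MHC class II was called higher for 8 of 8 (median 0.39, adjusted p = 0.00101, and adjusted p = 0.512 with an estimated correlation), with H2-Ab1 at 0.73 (SE 0.29). Mature T cell genes were called higher for 13 of 16 (median 0.40, adjusted p = 0.00116, and adjusted p = 0.52 with an estimated correlation), with the integrin gene Itgb7 at 0.78 (SE 0.22). Erythroid genes were called higher for 9 of 10 (median 0.11, adjusted p = 0.00068, adjusted p = 0.508 with an estimated correlation, 1 adjusted over the list alone), with Eraf at 0.21 (SE 0.05). Interferon response genes were called higher for 20 of 29 (median 0.10, adjusted p = 0.0181, and adjusted p = 0.733 with an estimated correlation), with Tap1 at 0.28 (SE 0.08). DNA repair genes were called higher for 23 of 29 (median 0.09, adjusted p = 0.011, and adjusted p = 0.549 with an estimated correlation), with Parp1 at 0.38 (SE 0.12). Heat shock and unfolded protein genes were called higher for 18 of 22 (median 0.19, adjusted p = 0.0181, adjusted p = 0.644 with an estimated correlation, 1 lower adjusted over the list alone). Ribosomal protein genes were called lower for 48 of 68 (median -0.10, adjusted p = 0.000144, adjusted p = 0.549 with an estimated correlation, 1 adjusted over the list alone), with Rpl24 at -0.32 (SE 0.08). Haemoglobin moved with these groups, Hbb-bt standing at 3.27 (SE 1.11). With haemoglobin as a covariate 5 of the 15 calls ended, those of B cells (adjusted p = 0.0501), erythroid (0.302), granulocyte (0.199), histone (0.182) and DNA repair genes (0.63). As the erythroid list itself holds haemoglobin genes, the end of its call says nothing further. The interferon call ended without 16 month replicate 1 (adjusted p = 0.343) or 6 month replicate 1 (0.0607) or 3 (0.0514), and the ribosomal call without 6 month replicate 2 (0.186). Without 16 month replicate 2 the calls of granulocyte (0.336), DNA repair (0.313) and heat shock genes (0.478) ended, and Chil3 stood at 0.15. Without 6 month replicate 3 those of DNA repair (0.129) and heat shock genes (0.387) ended.

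**Figure D3:**
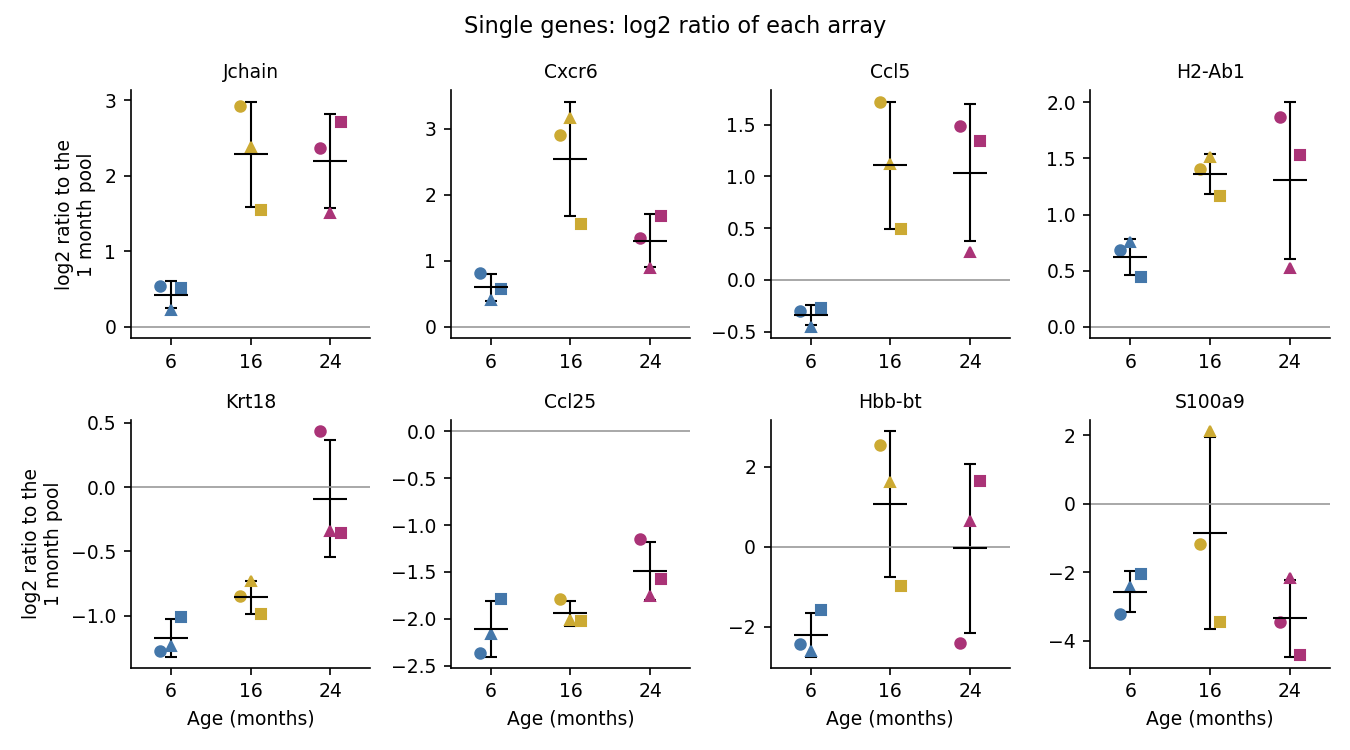
Each panel gives 1 gene, with age in months on the x axis and the log2 ratio to the 1 month pool on the y axis; circles, triangles and squares are replicates 1, 2 and 3, and the bar is the mean with its SD. Jchain averaged 0.43 (SD 0.18, n = 3) at 6 months, 2.29 (SD 0.70) at 16 months and 2.20 (SD 0.62) at 24 months, while Ccl25 lay below 0 on all 9 arrays.

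In limma 0 probes passed at 16 against 6 months (smallest adjusted p = 0.251). At an unadjusted p under 0.05 there were 3009, of which 1370 were higher and 1639 lower, against 1872 for chance and 3203 in a split of the 6 arrays that mixes the ages. Arrays did not overlap for 13.7% of the probes, where chance gives 10%. The genes with the smallest p, none of which passed, were Cxcr6, Jchain, Rps3a1 (-0.51, SE 0.09), Tiparp (-0.54, SE 0.10) and the chaperone gene Dnajb1 (-0.39, SE 0.08). The count was 0 in the other normalizations and filters, 2 without 16 month replicate 1, 4 without 16 month replicate 3 and 2 without the 3 arrays highest in haemoglobin. Without replicates 1, 2 and 3 of 16 months in turn 1, 3 and 0 of the 15 list calls ended, and 1, 1 and 3 without those of 6 months, among them the granulocyte call without 16 month replicate 2 (adjusted p = 0.336).

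The comparison of 24 with 16 months covers the last part of the age range. NK and cytotoxic genes were called lower at 24 months for 18 of 21 members (median -0.14, adjusted p = 0.000444, and adjusted p = 0.853 with an estimated correlation), with the perforin gene Prf1 at -0.23 (SE 0.08, and 0.10 with median centring). Granulocyte genes were called lower for 14 of 16 (median -0.25, adjusted p = 0.00316, and adjusted p = 0.853 with an estimated correlation), with S100a9 at -2.50 (SE 1.20). DNA repair genes were called lower for 25 of 29 (median -0.13, adjusted p = 0.000148, and adjusted p = 0.779 with an estimated correlation), with Parp1 at -0.39 (SE 0.12). Heat shock and unfolded protein genes were called lower for 19 of 22 (median -0.14, adjusted p = 0.0405, and adjusted p = 0.908 with an estimated correlation), with Hsph1 at -0.69 (SE 0.21). Apoptosis genes were called lower for 16 of 25 (median -0.06, adjusted p = 0.0405, and adjusted p = 0.847 with an estimated correlation). Proteasome genes were called lower for 27 of 36 (median -0.08, adjusted p = 0.0405, and adjusted p = 0.853 with an estimated correlation), with Psmb5 at -0.19 (SE 0.09). In the Cy3 channel alone the calls of NK and cytotoxic (adjusted p = 0.158), heat shock (0.158), apoptosis (0.118) and proteasome genes (0.396) ended. Without 16 month replicate 1 those of NK and cytotoxic (0.0851) and apoptosis genes (0.123) ended. Without 16 month replicate 2 those of granulocyte (0.528), heat shock (0.663) and proteasome genes (0.143) ended, and S100a9 stood at -1.02, Hsph1 at -0.43 and Psmb5 at -0.11. Without 16 month replicate 3 those of apoptosis (0.0933) and proteasome genes (0.0933) ended, and S100a9 stood at -3.81. The proteasome call also ended without 24 month replicate 1 (0.121) or 2 (0.338), the apoptosis call without 24 month replicate 2 (0.194), the heat shock call without 24 month replicate 2 (0.0532) or 3 (0.325), and the granulocyte call without 24 month replicate 3 (0.0769).

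Ribosomal protein genes were called higher at 24 against 16 months for 52 of 68 members (median 0.10, adjusted p = 0.000231, and adjusted p = 0.853 with an estimated correlation), with a median of -0.45 after median centring. Rpl13a stood at 0.17 (SE 0.06), and at -0.39 with median centring. Thymic epithelium genes were called higher for 8 of 14 (median 0.02, mean 0.15, adjusted p = 0.0255, and adjusted p = 0.853 with an estimated correlation), with Krt18 at 0.77 (SE 0.20) and Trp63 at 0.30 (SE 0.10). Adipocyte genes were called higher for 10 of 13 (median 0.05, adjusted p = 0.0405, and adjusted p = 0.779 with an estimated correlation), with Cd36 at 0.25 (SE 0.07) and Cfd at 0.22 (SE 0.08). Wnt pathway genes were called higher for 29 of 45 (median 0.05, adjusted p = 0.0113, and adjusted p = 0.779 with an estimated correlation). Adjusted over the list alone, 0 members passed in any of the 10 fixed lists called at 24 against 16 months. Immunoglobulin probes matched on their descriptions were called lower for 72 of 95 (median -0.17, adjusted p = 0.000452, and adjusted p = 0.918 with an estimated correlation). That direction turned without 16 month replicate 1 (adjusted p = 0.763). MHC class II genes had a median of 0.00, a mean of -0.02 and a test in the lower direction (adjusted p = 0.994). Haemoglobin was high on 16 month replicates 1 and 2 and on 24 month replicate 3. Leaving out these 3 arrays leaves 1 array of 16 months. There S100a9 stood at 0.65, and both the granulocyte list and the immunoglobulin probes by description turned to the higher direction. In the Cy3 channel alone the calls of ribosomal protein (adjusted p = 0.727), thymic epithelium (0.484), adipocyte (0.158), Wnt (0.118) and immunoglobulin by description (0.109) ended, so that 9 of the 11 list calls at 24 against 16 months did. The ribosomal (0.0563) and Wnt calls (0.0793) ended without 16 month replicate 1. The thymic epithelium call ended without 16 month replicate 3 (0.131) or 24 month replicate 1 (0.224), where Krt18 stood at 0.51. The adipocyte call ended without 16 month replicate 3 (0.157), 24 month replicate 1 (0.094) or 2 (0.0505) or 6 month replicate 1 (0.0507). Without 24 month replicate 2 the Wnt (0.0532) and immunoglobulin calls (0.134) ended.

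In limma 0 probes passed at 24 against 16 months (smallest adjusted p = 0.909). At an unadjusted p under 0.05 there were 1646, of which 552 were higher and 1094 lower, against 1872 for chance. Arrays did not overlap for 10.01% of the probes, where chance gives 10%. The genes with the smallest p, none of which passed (adjusted p = 0.909), were the kinase gene Prkca (-0.26, SE 0.05), Crip3 (0.28, SE 0.06), Rbm3 (0.83, SE 0.17) and Dnajb1 (0.33, SE 0.08, and -0.07 with median centring). Prkag3, not well above background on any 16 month array, was at least 1.14-fold higher. The count was 0 in the other normalizations and filters and 2 without the 3 arrays highest in haemoglobin. With haemoglobin as a covariate 2 of the 10 list calls ended, those of thymic epithelium (adjusted p = 0.06) and the proteasome (adjusted p = 0.0879). Without replicates 1, 2 and 3 of 16 months in turn 4, 3 and 4 of the 10 list calls ended, and 3, 5 and 2 without those of 24 months, among them the granulocyte call without 16 month replicate 2 (adjusted p = 0.528).

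The test for any difference among 6, 16 and 24 months passed 0 probes in limma (smallest adjusted p = 0.607), with 2672 at an unadjusted p under 0.05. The 5 genes with the smallest p were Psma4, Tmem107, Kcnj12, Rps3a1 and Zfp574, at an adjusted p of 0.696, and none passed. The count was 2 without 16 month replicate 1, 3 without 16 month replicate 3 and 1 without the 3 arrays highest in haemoglobin.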

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

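The tests of explanations in this part were chosen after the results were seen. Single channels were compared within the group of 9 1 month channels, where chance alone sets 1 in 20 groups apart. On 6 month replicate 1 the 1 month channel lay apart from the other 8, with 90.5% of features well above background and a Cy5 dye factor of 5.31. A probe of Hbb-b1 lay apart in the 1 month channel of 16 month replicate 1, at a log2 level of 12.2. For 3 gene lists all arrays of 6 months lay on the opposite side of the pool from all arrays of an older age. The difference between these means was not tested by itself, while camera compared each list with all other genes. The macrophage list averaged 0.20 at 16 months and -0.12 at 6 months, 0.32 apart (camera adjusted p = 0.000376, and 0.512 with an estimated correlation). The adipocyte list averaged 0.10 at 24 months and -0.01 at 6 months, 0.11 apart (camera adjusted p = 0.0832). The regulatory T cell list averaged 0.03 at 16 months and -0.05 at 6 months, 0.074 apart (camera adjusted p = 0.519).

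Immunoglobulin probes matched on their descriptions averaged 0.70 higher at 16 than at 6 months (95% interval 0.17 to 1.23) and 0.50 higher at 24 months (-0.02 to 1.03), so that the latter alone does not exclude 0. With the Cy3 signal as a covariate 0.69 (SE 0.23) remained at 16 months, which argues against weaker signal as the whole source. The median Cy3 signal over background of the 16 month arrays (109 to 115) lay within that of the 6 month arrays (77.1 to 175). At 24 months the difference was 0.56 (SE 0.24) with this covariate and 0.50 without it, so the covariate did not lower it. Its interval included 0 either way (-0.07 to 1.19 with the covariate), so the 24 month difference is too imprecise to decide. With haemoglobin as a covariate the differences were 0.54 (SE 0.31) and 0.40 (SE 0.27), so that the wider error spans both 0 and the uncorrected value, and RNA from blood cannot be told apart from age, although 24 month replicate 1, with haemoglobin at -1.71, had immunoglobulin at 0.76. The ages were weighed separately here after a first version that asked for both at once had given no decision. More B cells and plasma cells in the suspension may account for it and are not excluded by a B cell list median of 0.12 at 24 against 6 months, and age itself stays open as an untested biological explanation.

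Haemoglobin ranged widely over the arrays, from a mean log ratio of -1.75 on 6 month replicate 1 to 1.78 on 16 month replicate 1. A change in the 1 month channel is argued against, since the 2 Hbb-bt probes ranged over 0.51 and 0.15 in the 1 month channels and over 4.67 and 5.17 in the Cy3 channels. A candidate explanation is red cells left after the ammonium chloride lysis in some suspensions, as the mean of 8 other erythroid genes followed haemoglobin over the 9 arrays with a Pearson r of 0.95 (exact permutation p = 7.44e-05) and a Spearman rho of 0.97 (exact permutation p = 0.000165), and r was 0.90 without the 2 arrays farthest from the median. Alas2 moved most (range 1.94, r of 0.96), the other 7 genes ranged over 0.19 to 0.50 with r from 0.05 (Klf1) to 0.79 (Slc4a1), and their mean without Alas2 gave an r of 0.84 (exact permutation p = 0.00717), a rho of 0.85 (exact permutation p = 0.00607) and an r of 0.70 without the same 2 arrays. These permutations ignored age. All 6 month arrays were below 0 in haemoglobin (-1.75, -1.73 and -1.09) and in the mean of the 8 genes (-0.15, -0.14 and -0.09). A difference between ages therefore enters these correlations and their p. Within each age both measures ranked the arrays alike, which was not tested by itself. Age stays open as well. The erythroid list was called higher at 24 and 16 than at 6 months (adjusted p = 0.00824 and 0.00068, and 0.339 and 0.508 with an estimated correlation). That list of 10 includes haemoglobin genes besides the 8 others, so its calls are not separate support for age.

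Between 6215 and 9131 probes passed against the 1 month pool at each age, where dye and age go together. For immunoglobulin at 16 months a dye difference is argued against by the 0.70 between 16 and 6 months, where the dyes cancel. For the other 8008 probes past the threshold at 24 months it cannot be told apart from age, since 18.3% of them (1465) had an unadjusted p under 0.05 between 24 and 6 months, and a low share also follows from a change before 6 months. Saturated spots are argued against for most of the calls at 24 months, as 62 of the 8046 probes past the threshold were saturated on any array. These parts were likewise split from a first version that had given no decision, and age stays open as untested.

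At 3 arrays against 3 the 10 splits are too few to exclude chance at a share under 0.05. At 24 against 6 months the real split had 0 probes and 17 lists called, and the highest other values were 0 and 18. At an unadjusted p under 0.05 the real split had 3192 probes and the highest other 2430. At 16 against 6 months the real split had 0 and 15, with 0 and 11 as the highest others, and 3009 probes unadjusted against 3203. At 24 against 16 months the real split had 0 and 10, and 1646 probes unadjusted. There the highest other probe counts were 554, and 5124 unadjusted, in the split that sets 16 month replicates 1 and 2 and 24 month replicate 3 apart, which points to a structure of the samples. The highest other list count, 23, came in a different split, which passed 1 probe. For the test among the ages, the real partition had 0 probes, a count that any partition reaches, and the highest of 100 drawn partitions had 991. At an unadjusted p under 0.05 the real one had 2672 and the highest other 5709, and 14 of the 100 had as many, the real one included, so that chance is not excluded.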

How the results depend on the processing

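The alternatives without saturated probes, without the 2 arrays standing apart (16 month replicate 1 and 24 month replicate 3), without the 3 arrays highest in haemoglobin and with haemoglobin as a covariate were added after seeing the data. The others were planned before. A planned scan date block was not run. Only the extraction day was read, which all arrays share, and it does not exclude separate scan or hybridization days. Of the 147 named gene values, the 82 against the pool had passed the threshold and the 65 between the older ages had not. Between the older ages at most a few probes passed in any setting, so for those 65 keeping the side of the threshold says little. Of all 147, 144 kept their direction and side of the threshold with Agilent's processed signals and 116 with median centring. It was 141 with the replicate block and 140 with the authors' scores. It was 129 with haemoglobin as a covariate, 131 without the 2 arrays and 107 without the 3. It was 130 of 142 with only the compared ages in the fit, 65 of 65 in the Cy3 channel alone, 82 of 82 in the separate-channel fit, 146 with scale normalization and 146 with an intensity trend. The 82 of 82 says little if the reference is 1 pool, since that fit counted the 9 Cy5 channels as 9 samples. The number kept was 147 without a filter on dim probes, 135 of 135 with a strict one, 147 with outlier spots kept and 145 of 145 without saturated probes. Of 72 list calls 64 did so with Agilent's signals, 42 with median centring, 71 with the replicate block, 54 with haemoglobin as a covariate, 51 without the 2 arrays, 46 without the 3 and 0 with an estimated correlation. It was 67 without a filter on dim probes, 65 with the mean over all probes of a gene and 68 without saturated probes. In the Cy3 channel alone 32 of the 45 list calls between the older ages did so, and of the 13 that ended, 4 were at 24 against 6 months and 9 at 24 against 16 months. The Cy3 signal over background, lowest on 24 month replicate 2 (61.2), limits what can be seen in dim probes. Unless the fewer arrays of a setting account for a change, the cause was not tested.

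Median centring shifts each array by 1 value, so a dye difference that changes with intensity stays in the log ratios. With median centring 19624 probes passed at 6 months, 16652 at 16 months and 26554 at 24 months against the pool, and 54 of the 82 named genes past the threshold stayed past it. The directions of 8 genes turned: at 24 against 16 months Dnajb1 (-0.073), Prf1 (0.10) and Rpl13a (-0.39), at 6 months Lat (-0.14), Ly6d (-0.093), Satb1 (-0.38) and Hspa8 (-0.082), and at 24 months Hspa8 (-0.57). The direction of the list test, which is relative to all other genes, turned for 13 lists, with the adjusted p given here. They were ribosomal proteins at 24 against 16 months (2.18e-13), 6 months (0.0012) and 24 months (1.95e-07) against the pool, double-positive thymocytes at 6 (0.241) and 16 months (0.286), the T cell receptor complex at 6 (0.307) and 16 months (0.353), heat shock at 6 (0.780) and 24 months (0.345), histones at 6 months (0.780), DNA repair at 16 months (0.365), and receptor segments by description at 6 (0.779) and 24 months (0.186). Mature T cells at 24 against 6 months turned in median (-0.02) and mean (-0.06) while the test kept its direction (0.855). In contrast, 0 of the 147 named gene values turned with Agilent's processed signals, scale normalization or the authors' scores. Of the 72 list calls, 0 turned with Agilent's processed signals.

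With a replicate block 3928 probes passed at 6 months against the pool, and with haemoglobin as a covariate 844. With only the compared ages in the fit, 1 probe passed at 24 against 6 months, 4320 at 16 months and 4152 at 24 months against the pool. A separate-channel fit, which counted the 9 Cy5 channels as 9 samples, passed 9358 at 6 months. With an estimated correlation 0 lists were called between the older ages (42 with the preset one) and 0 against the pool (23). Without saturated probes the ribosomal list at 24 months against the pool turned (adjusted p = 0.844). Without the 2 arrays standing apart the immunoglobulin probes by description turned at 24 against 16 months (adjusted p = 0.544).

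Leaving out the 3 arrays highest in haemoglobin leaves 1 array of 16 months, which is assumed to vary like the others. There 2 probes passed at 16 against 6 months, 2 at 24 against 16 months, 1 among the ages, 13 at 16 months and 4615 at 24 months against the pool, and 43 named genes stayed past the threshold. S100a9 at 24 against 16 months turned to 0.65. Granulocytes turned at 16 against 6 months (adjusted p = 0.684) and at 24 against 16 months (0.122), as did immunoglobulin by description at 24 against 16 months (1.79e-09).

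Leaving out 1 array at a time, 0 to 2 probes passed at 24 against 6 months, 0 to 4 at 16 against 6 months, 0 to 0 at 24 against 16 months and 0 to 3 among the ages. The 2 came without 16 month replicate 3, which also gave the 4 (among them Cxcr6) and the 3, while 16 month replicate 1 gave 2 at 16 against 6 months and 2 among the ages. Against the pool 489 to 6504 passed at 6 months, 2561 to 9452 at 16 months and 2352 to 8138 at 24 months. The 6 month count was 2070 without replicate 1 and 489 without replicate 2. At 16 months it was 2561 without replicate 2 and 5055 without replicate 3, and at 24 months 2352, 4323 and 5059 without replicates 1, 2 and 3. Lists called ranged from 33 to 47 between the older ages and from 19 to 31 against the pool, and named genes past the threshold from 61 to 79. The interferon list at 24 against 6 months turned without 24 month replicate 1 (adjusted p = 0.795, over a range from 1.17e-05), and immunoglobulin by description at 24 against 16 months turned without 16 month replicate 1 (0.763, over a range from 1.96e-17).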

Other observations

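The comparison below was made after the splits of the arrays had been seen, and its genes and lists were chosen after their values were seen. Of the 6 arrays of 16 and 24 months, the 3 highest in haemoglobin (16 month replicates 1 and 2 and 24 month replicate 3) were set against the other 3. The 3 did not all correlate best with each other. Log ratios of 16 month replicate 1 and 24 month replicate 3 correlated at 0.75. Those of 16 month replicate 2 correlated with these 2 at 0.67 and 0.70, and with 16 month replicate 3 of the other side at 0.72. This split was taken because it passed the most probes of the 10 splits of these arrays, so its adjusted p are not corrected for that choice. In limma 554 probes passed between the 2 sides, 62 higher and 492 lower on the high arrays. Rag1, the recombinase gene that rearranges T cell receptor segments in thymocytes, stood at -1.58 (SE 0.12, adjusted p = 0.00389), with all 3 arrays below the others. Ramp2 (-1.24, SE 0.12), Foxn3 (-0.81, SE 0.08), Zc3h15 (-0.68, SE 0.06) and Ppp4r3b (-0.58, SE 0.05) were lower in the same way.

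In this split 10 of the 38 fixed lists were called, as many as at the real split by age (10), while other splits of the 6 arrays called 17, 18 and 23. NK and cytotoxic genes were called higher on the 3 arrays for 21 of 21 members (median 0.17, adjusted p = 9.32e-06, and adjusted p = 0.884 with an estimated correlation), as were plasma cell (median 0.17, adjusted p = 0.0035, and adjusted p = 0.884 with an estimated correlation), immunoglobulin (median 0.27, adjusted p = 0.0236, and adjusted p = 0.911 with an estimated correlation), granulocyte (median 0.28, adjusted p = 0.0392, and adjusted p = 0.933 with an estimated correlation), DNA repair (median 0.11, adjusted p = 0.00801, and adjusted p = 0.911 with an estimated correlation) and proteasome genes (median 0.09, adjusted p = 0.044, and adjusted p = 0.911 with an estimated correlation). Erythroid genes were also called higher (median 0.06, adjusted p = 0.0217, and adjusted p = 0.553 with an estimated correlation), on arrays that are the highest in haemoglobin. Replication-dependent histone (median -0.24, adjusted p = 1.45e-07, and adjusted p = 0.478 with an estimated correlation), ribosomal protein (median -0.12, adjusted p = 0.00159, and adjusted p = 0.933 with an estimated correlation) and immediate early genes (median -0.08, adjusted p = 0.044, and adjusted p = 0.933 with an estimated correlation) were called lower. Double-positive thymocyte genes were not called (median 0.07, adjusted p = 0.74). The arrays were not grouped this way by the design.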
